A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

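RNA was measured in 18 libraries, 3 for each of 2 strains (RM11, YJM975) in each of 3 media (2% glucose, glycerol or ethanol). Per the labels' protocols, cells were snap-frozen and RNA extraction, polyA enrichment and library preparation were done at a sequencing institute. The deposited table holds TPM, estimated transcript abundances scaled by length and to a fixed total per library, and kallisto is named in the submitters' processing notes. The version of kallisto, its settings and the transcript sequences it used are not given in the sources used here. kallisto divides reads among similar transcripts by their likelihood, so levels of near-identical genes depend on how reads were split, and transcripts that diverge from the sequences used can receive fewer reads. TPM keeps no depth, so a library's depth and the counting error of a gene are unknown, and a rise in abundant transcripts lowers all others. Per the series design the triplicates are biological.

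Transcript names were matched to a table of assembly R64 of strain S288C, and 5929 matched by locus name, 683 did not. That assembly was used for names, coding lengths, neighbours and copies, and no coordinates are given. Genes aligned by BLAST (2.17.0) at 95% identity over 50% of their length were taken as near-identical copies, 221 in all and 146 among the tested. In addition, 123 tested genes overlap another. Transcripts absent from the annotation of that assembly were not searched for copies or overlaps, so theirs are unknown. In all, 124 transcripts stood at 0 in every library. No column of the table was left unused.

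Genes with a mean of at least 1 TPM over the 18 libraries were tested, 6309 in all, of which 5778 (91.6%) have a coding length. The test was limma (3.58.1, R 4.3.3) on log2(TPM + 1), with 1 fit of 6 group means over all libraries (12 residual degrees of freedom), empirical Bayes with a mean-variance trend and Benjamini-Hochberg adjustment within each contrast. A gene was called at an adjusted p below the threshold of 0.05. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. The 13 contrasts were YJM975 minus RM11 in each medium and averaged over the media, the 3 pairs of media in each strain, and the 3 differences of these between the strains (YJM975 change minus RM11 change). Because TPM is relative, the median change of all genes is given for each contrast, and list medians are given relative to it.

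Gene lists were fixed before the data were examined, as were the contrasts, the tests and the alternative settings. Of 36 lists, 35 had at least 4 tested members and were tested in each contrast with camera at a preset correlation of 0.01, 455 tests with adjustment within each contrast. Of these 205 were called, and 11 were called with the correlation estimated per list. The cytosolic ribosomal protein list was set by a pattern of gene names. It also took in RPP1, an RNase P subunit gene and not a ribosomal protein gene. Counts of called members are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time. Per contrast it takes the 6 genes with the largest rise and the 6 with the largest fall among called genes at 10 TPM or more in the higher group, whose libraries do not overlap between the groups (no overlap rule for averages and differences of responses). From each described list it takes up to 4 called members with the largest change, or any member of lists of up to 10 genes, and it adds a set of reference genes of carbon metabolism and of known strain differences. FLO8, a reference gene, was not analysed here. No overlap between 3 and 3 libraries arises by chance for 10% of unchanged genes.

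Replicates were compared across genes (r 0.9945 to 0.9977) and no pair of libraries held identical values. Simulated data for the strain difference in glucose, with 6309 genes, gave back 66 of 67 genes changed 1.5-fold (98.5%), 67 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 10 false calls among 6109 unchanged genes, 4.8% of the calls. The simulation used independent noise, changed few genes and did not rescale to a fixed total, so errors from that scaling were not covered. Changed genes were drawn only from those above about 5 TPM in RM11 in glucose, so recovery of lower genes was not covered either. The alternative settings fixed then were pseudocounts of 0.1 and 5, no filter, a filter at 10 TPM, median centring, quantile normalization, rescaling without the 50 most abundant genes, fits on the groups compared only, the replicate number as a block, empirical Bayes without trend or robust, library weights, and leaving out each library in turn. Removal of a trend with coding length, fits without the glucose libraries, and camera with a variance trend were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9.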

Results

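Messenger RNA was measured in 18 cultures of the budding yeast Saccharomyces cerevisiae. The cultures came from 2 strains, RM11, derived from a vineyard isolate, and YJM975, a clinical isolate, both as homozygous diploids. Each strain was grown in synthetic medium with a complete supplement mixture and 2% glucose, glycerol or ethanol, which gave 6 groups of 3 replicate cultures. Per the labels, cultures of 5 mL were sampled in exponential growth at an optical density of 0.5 to 1.0 and polyadenylated RNA was sequenced. The series names these as parental strains in a study of heritable traits, and the comparisons are between the strains in each medium, between the media in each strain, and between the strains' responses to a medium. The glucose libraries of both strains carried 1 sequencing run label and the glycerol and ethanol libraries another.

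The table gives transcript abundance as TPM, scaled to a fixed total, in each library. Each library sums to 1000000 TPM within 1 TPM, so its depth is unknown and no counting interval can be given. Replicates of a group correlated with r between 0.9945 and 0.9977 across genes, which are not independent replicates. The first principal component of the 6309 tested genes held 56.06% of the variance and the second 20.01%. Levels below are mean TPM ± SD over 3 libraries, and changes are log2 differences of TPM + 1 ± SE from limma.

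**Figure D1:**
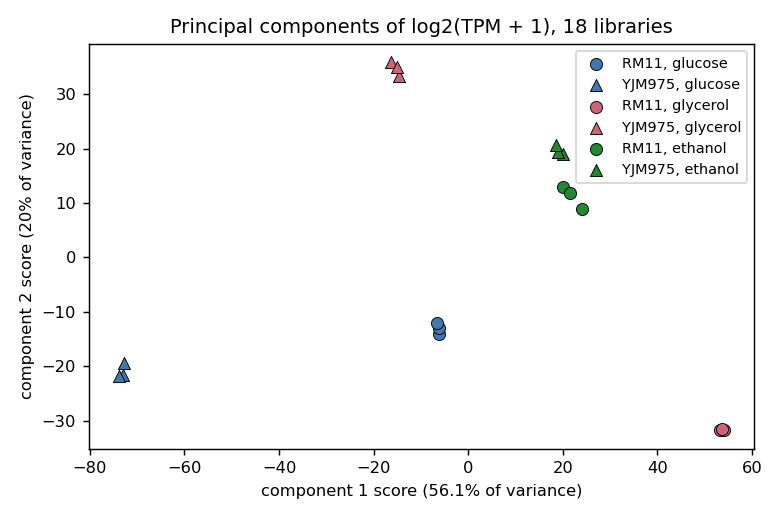
Scores of the 18 libraries on the first (x axis, 56.06% of variance) and second (y axis, 20.01% of variance) principal components of log2(TPM + 1), 1 point per library, with colour for the medium and symbol for the strain. The 3 libraries of each group lie together, and the RM11 and YJM975 groups lie closer in ethanol than in glucose or glycerol.

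SIP18 and DDR2 held the highest mean TPM of all transcripts over the 18 libraries. SIP18, a phospholipid-binding gene induced by desiccation and osmotic stress, stood at 52945 ± 2045 TPM in RM11 and 12084 ± 282 TPM in YJM975 in the libraries labelled glucose, and between 50477 and 94059.6 TPM as group means in the others. DDR2, a gene of the general stress response, ranged from 34017 to 65701 TPM over the group means. SIP18 and DDR2 were chosen for this description after their values were seen. Cytosolic ribosomal protein genes took 6.55 ± 0.264% of all TPM in RM11 and 2.87 ± 0.028% in YJM975 in glucose (SD, n = 3), 12.3 ± 0.292% and 5.67 ± 0.176% in glycerol, and 9.84 ± 0.216% and 10.8 ± 0.455% in ethanol. HXK2, the glucose-induced hexokinase, stood at 2.30 ± 0.0468 TPM in RM11 and 5.08 ± 0.534 TPM in YJM975 in the libraries labelled glucose. In those libraries ICL1, the isocitrate lyase of the glyoxylate cycle, stood at 1791 ± 107 TPM in RM11 and 401 ± 36.0 TPM in YJM975. FBP1, the gluconeogenic fructose-1,6-bisphosphatase, stood there at 809 ± 29.3 and 353 ± 24.0 TPM, above its means of 249.9 and 198 TPM in ethanol. Both are textbook genes of repression by glucose, so the medium of every library is given as labelled throughout.

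In the libraries labelled glucose, YJM975 held less mRNA for ribosomes, glycolysis and sterol synthesis than RM11 and more for heat shock proteins. Of 139 cytosolic ribosomal protein genes, 134 were lower and 3 higher in YJM975, with a median log2 difference of -1.88, or -1.50 relative to all genes (camera adjusted p = 9.52e-16, or 0.767 with an estimated correlation). RPS24B, of the 40S subunit and near-identical to RPS24A, differed by -3.50 ± 0.05. All but 1 of the 23 sterol synthesis genes were lower, at -1.09 relative to all genes (camera adjusted p = 2.64e-04, or 0.767 with an estimated correlation). They included ERG3, the C-5 sterol desaturase, at -3.83 ± 0.09, ERG25, the C-4 methyl sterol oxidase, at -3.30 ± 0.06 and ERG11, the lanosterol demethylase, at -3.12 ± 0.07. Glycolysis and fermentation genes were lower for 19 of 21 (camera adjusted p = 0.00839, or 0.868 with an estimated correlation), among them the phosphoglycerate kinase gene PGK1, from 329.6 ± 9.58 TPM in RM11 to 38.6 ± 4.03 TPM in YJM975, and the glyceraldehyde-3-phosphate dehydrogenase gene TDH3, near-identical to TDH2, at -2.49 ± 0.07. In ribosome biogenesis 33 of 39 genes were lower (camera adjusted p = 0.00237, or 0.767 with an estimated correlation), with the nucleolar protein gene NOP56 at -2.46 ± 0.07.

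Heat shock proteins and chaperones were higher in YJM975 for 21 of 27 genes in the same libraries, at 0.90 relative to all genes (camera adjusted p = 5.22e-07, or 0.767 with an estimated correlation). HSP82, an Hsp90 chaperone gene, differed by 1.11 ± 0.07 and the small heat shock gene HSP42 by 1.08 ± 0.06. Trehalose and glycogen genes were higher for 13 of 20 (camera adjusted p = 8.96e-05, or 0.847 with an estimated correlation), led by the glycogen synthase gene GSY1 at 1.84 ± 0.08. Electron transport chain genes encoded in the nucleus were higher for 16 of 23 (camera adjusted p = 1.32e-06, or 0.147 with an estimated correlation). The largest of these were CYC7, the minor cytochrome c, at 2822 ± 74.8 TPM against 236 ± 6.29 TPM, and COX5B, at 2.46 ± 0.06. Among 21 cyclin and cell cycle genes, 18 were lower (camera adjusted p = 0.0494, or 0.868 with an estimated correlation), with PCL1 at -3.73 ± 0.08 and CLN1 at -3.66 ± 0.07. DPA10 was lower, from 5782 ± 252 TPM in RM11 to 40.7 ± 23.7 TPM and the biotin synthesis gene BIO4 from 258 ± 13.2 to 9.51 ± 1.01 TPM. The counts of these lists adjusted over the list alone were the same except for heat shock proteins and chaperones (22 higher and 5 lower). In all, limma called 5244 of 6309 genes at a Benjamini-Hochberg adjusted p below the threshold of 0.05, 1417 higher and 3827 lower, or 2607 and 2663 with median centring. The median gene differed by -0.38, and 245 genes were higher and 1479 lower by 2-fold or more, or 644 and 862 with median centring.

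In glycerol, single genes differed widely between the strains, and most meiosis and sporulation genes were lower in YJM975. FLO11, the cell-surface flocculin of filamentous growth and biofilms, stood at 2890.0 ± 109 TPM in YJM975 and 8.75 ± 1.16 TPM in RM11, a log2 difference of 8.22 ± 0.09 (limma adjusted p = 5.41e-20). SPS4, a sporulation-specific gene, stood at 636 ± 48.8 TPM in RM11 and 0.592 ± 0.0995 TPM in YJM975, a difference of -8.64 ± 0.30 (limma adjusted p = 1.54e-14). Of 28 meiosis and sporulation genes, 24 were lower in YJM975 (camera adjusted p = 0.00756, or 0.425 with an estimated correlation), among them the protein kinase gene SPS1 at -4.43 ± 0.13, SSP2 at -4.01 ± 0.08 and the meiosis I regulator SPO13 at -3.97 ± 0.11. ZRT1, the high-affinity zinc transporter, was higher in YJM975 by 4.42 ± 0.07.

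Genes for making ribosomes were lower and genes for respiration higher in YJM975 than in RM11 in glycerol. All 39 of 39 ribosome biogenesis genes were lower, at -1.90 relative to all genes (camera adjusted p = 3.90e-08, or 0.275 with an estimated correlation), including the RNA helicase DBP2 at -3.79 ± 0.12, the RNA polymerase I subunit RPA49 at -3.77 ± 0.09 and the nucleolin NSR1 at -3.49 ± 0.31. The 139 of 139 cytosolic ribosomal protein genes that were lower lay at -0.66 relative to all genes (camera adjusted p = 5.60e-09, or 0.425 with an estimated correlation). ATP synthase genes were higher for 17 of 17 (camera adjusted p = 1.16e-11, or 0.0261 with an estimated correlation) and electron transport chain genes for 19 of 23 (camera adjusted p = 2.45e-12, or 0.0124 with an estimated correlation). Examples are the cytochrome c oxidase subunits COX13, at 1.31 ± 0.05, and COX7, at 1.14 ± 0.05, and the ATPase inhibitor-stabilizing factor STF1, at 1.05 ± 0.07. Quiescence and starvation markers were higher for 17 of 21 (camera adjusted p = 3.12e-12, or 0.0967 with an estimated correlation), with SPG1 at 1.86 ± 0.05, and heat shock genes for 21 of 27 (camera adjusted p = 2.45e-12, or 0.283 with an estimated correlation). All 21 of 21 cyclin and cell cycle genes (camera adjusted p = 0.00143, or 0.425 with an estimated correlation) and 10 of 10 histone genes (camera adjusted p = 0.0217, or 0.418 with an estimated correlation) were lower, such as the ribonucleotide reductase gene RNR1 at -3.20 ± 0.08 and the histone H2B gene HTB2 at -2.88 ± 0.06. HXK2 stood at 71.3 ± 6.78 TPM in RM11 and 1.84 ± 0.316 TPM in YJM975. Counts adjusted over the list alone were the same. The total was 5440 called genes, 1020 higher and 4420 lower, or 2643 and 2607 with median centring, and the median gene differed by -0.59. By 2-fold or more 195 were higher and 1984 lower, or 680 and 886 with median centring.

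In ethanol, 3027 genes were called between the strains by limma, 1692 higher and 1335 lower in YJM975, of which 144 and 154 by 2-fold or more, and with median centring 1576 were higher and 1700 lower. The order of the strains in ribosome biogenesis was the opposite of that in glycerol, with 38 of 39 genes higher in YJM975, at 0.56 relative to all genes (camera adjusted p = 1.25e-14, or 0.0675 with an estimated correlation), such as NSR1 at 1.53 ± 0.31 and DBP2 at 1.48 ± 0.12. Purine and uracil synthesis genes were higher for 15 of 22 (camera adjusted p = 2.98e-05, or 0.462 with an estimated correlation), including ADE4, of the first step of purine synthesis, at 1.28 ± 0.05 and the IMP dehydrogenase gene IMD4 at 1.28 ± 0.10. Genes of the electron transport chain were lower for 21 of 23 (camera adjusted p = 7.61e-10, or 0.0353 with an estimated correlation), led by both cytochrome c genes, CYC1 at -1.91 ± 0.05 and CYC7 at -1.51 ± 0.06. Of 21 cyclin and cell cycle genes 18 were lower in YJM975 (camera adjusted p = 2.44e-12, or 0.0675 with an estimated correlation), with PCL1 at -2.83 ± 0.08 and CLN1 at -2.24 ± 0.07. So were 9 of 10 histone genes (camera adjusted p = 6.38e-05, or 0.0857 with an estimated correlation). Sucrose and maltose genes were lower for 11 of 12 (camera adjusted p = 7.61e-10, or 0.0675 with an estimated correlation), with the invertase SUC2 at -2.09 ± 0.09. For these lists, the counts adjusted over the list alone were the same.

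Averaged over the media, large strain differences included the transporter gene HXT7, maltose genes and short open reading frames. HXT7, a high-affinity hexose transporter, stood at 81.4 ± 6.22, 379.9 ± 62.8 and 54.0 ± 1.62 TPM in RM11 in glucose, glycerol and ethanol, and at 0.261 ± 0.349, 0.0850 ± 0.0337 and 0.0907 ± 0.0352 TPM in YJM975. Its near-identical neighbour HXT6 was higher in YJM975, at 1693 ± 131, 648 ± 98.6 and 914 ± 168 TPM against 587 ± 49.7, 198 ± 29.0 and 233 ± 24.1 TPM, so the split of reads between the pair is uncertain; HXT6 was chosen after its values were seen. MAL11, an alpha-glucoside permease, averaged -4.57 ± 0.05 and the maltose activator MAL13 -3.77 ± 0.04. The maltase MAL32, whose near-identical copy MAL12 stayed below 1 TPM in every library, averaged -4.76 ± 0.06, and SUC2 averaged -2.08 ± 0.05. All 12 of 12 sucrose and maltose genes were lower in YJM975 (camera adjusted p = 0.00548, or 0.451 with an estimated correlation). YHR052W-A and YHR054W-A, 2 short frames with identical values in every library, stood at 220.3 ± 21.4, 222 ± 14.6 and 308 ± 6.45 TPM in YJM975 in glucose, glycerol and ethanol, and at no more than 0.688 TPM in any RM11 library.

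Heat shock genes were higher in YJM975 on average for 22 of 27 (camera adjusted p = 9.76e-14, or 0.443 with an estimated correlation), with HSP42 at 1.11 ± 0.03. Cytosolic ribosomal protein genes were lower for 135 of 139 (camera adjusted p = 6.49e-12, or 0.451 with an estimated correlation), with RPL29 at -2.67 ± 0.07, cell cycle genes for 20 of 21 (camera adjusted p = 6.05e-04, or 0.451 with an estimated correlation), with CLN1 at -2.99 ± 0.04, and meiosis genes for 26 of 28 (camera adjusted p = 0.00430, or 0.480 with an estimated correlation), with the cohesin subunit REC8 at -2.20 ± 0.05. In ethanol alone, cytosolic ribosomal protein genes took a larger share of all TPM in YJM975 than in RM11 (10.8% against 9.84%). The counts of these lists adjusted over the list alone were the same except for heat shock proteins and chaperones (23 higher and 3 lower). The average called 5344 genes, 970 higher and 4374 lower, or 2535 and 2745 with median centring, and the median gene differed by -0.34. In all 3 media, 36 genes were higher and 68 lower in YJM975 by 2-fold or more. Across genes, which are not independent replicates, the strain differences in glucose and glycerol correlated with r = 0.313, those in glucose and ethanol with r = 0.278 and those in glycerol and ethanol with r = 0.158. The rank correlations (Spearman) were 0.304, 0.099 and -0.1. For glycerol and ethanol, 1579 genes were called in opposite directions. Calls shared by these 2 media, 263 higher and 887 lower, were fewer than independent lists would share (273.6 and 935.3).

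**Figure D2:**
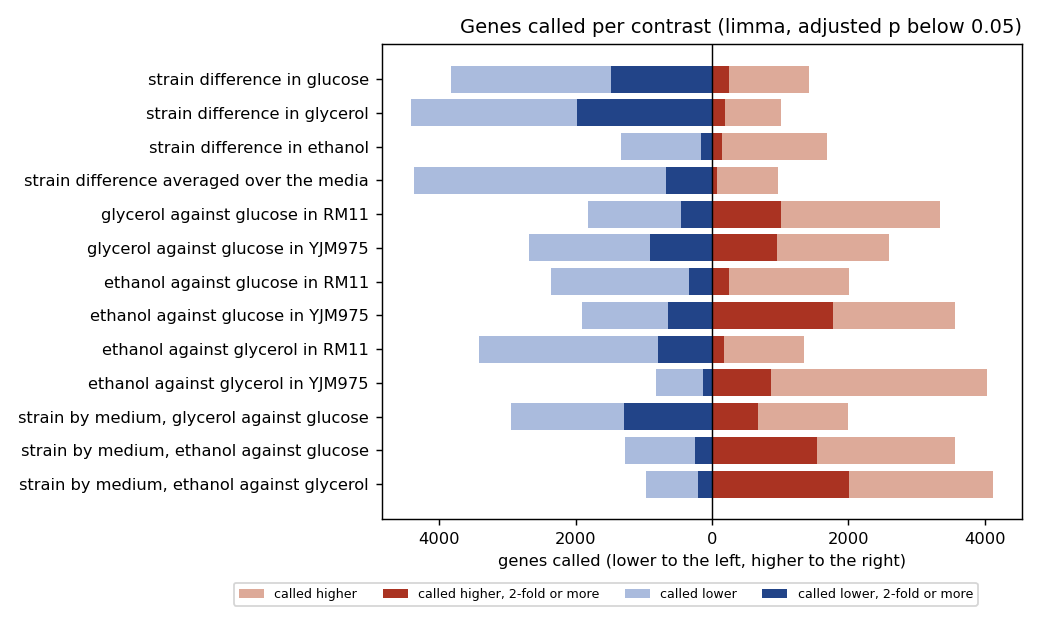
Number of genes called (x axis) in each of the 13 contrasts (y axis), lower to the left and higher to the right of 0, with the darker part of each bar for changes of 2-fold or more. The strain difference called 298 genes at 2-fold or more in ethanol, against 1724 in glucose and 2179 in glycerol.

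In RM11, glycerol libraries held more mRNA for sporulation, fermentation and ribosomes than the libraries labelled glucose, and less for respiration and the heat shock response. SPS4 rose from 0.101 ± 0.0398 to 636 ± 48.8 TPM, the cell wall mannoprotein gene TIP1 by 7.27 ± 0.07 and the sporulation gene SPR2 by 5.82 ± 0.18. Of 28 meiosis and sporulation genes 25 rose, at 1.48 relative to all genes (camera adjusted p = 4.81e-06, or 0.252 with an estimated correlation), with the septin SPR3 at 3.94 ± 0.10. PDC1, the main pyruvate decarboxylase, rose by 4.76 ± 0.08, the enolase ENO2 by 4.68 ± 0.09 and HXK2 by 4.45 ± 0.12, with 17 of 21 genes of glycolysis and fermentation higher (camera adjusted p = 0.00314, or 0.559 with an estimated correlation). ADH2, the alcohol dehydrogenase that consumes ethanol, rose from 144 ± 16.3 to 1686 ± 122 TPM. Ribosome biogenesis genes rose for 39 of 39 (camera adjusted p = 2.08e-09, or 0.220 with an estimated correlation) and cytosolic ribosomal protein genes for 137 of 139 (camera adjusted p = 2.51e-13, or 0.389 with an estimated correlation). The membrane stress gene HSP30 fell from 1828 ± 118 to 16.6 ± 1.30 TPM and the small heat shock gene HSP26 changed by -4.07 ± 0.05, in a list with 24 of 27 lower (camera adjusted p = 1.63e-11, or 0.349 with an estimated correlation).

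Mitochondrial genes were lower together in RM11 libraries labelled glycerol than in those labelled glucose, whose medium is in doubt from the levels of HXK2, ICL1 and FBP1. Mitochondrial ribosomal protein genes were lower for 72 of 73, at -1.01 relative to all genes (camera adjusted p = 3.45e-22, or 0.0224 with an estimated correlation), electron transport chain genes for 21 of 23, at -1.50 (camera adjusted p = 6.82e-12, or 0.0154 with an estimated correlation), and ATP synthase genes for 17 of 17, at -1.43 (camera adjusted p = 5.21e-11, or 0.0224 with an estimated correlation). The cytochrome bc1 subunit QCR9 changed by -1.96 ± 0.05 and the ATP synthase subunit ATP20 by -1.84 ± 0.05. Glyoxylate cycle and gluconeogenesis genes were lower for 11 of 14 (camera adjusted p = 2.56e-05, or 0.505 with an estimated correlation), with the malate synthase MLS1 at -2.85 ± 0.08, FBP1 at -2.36 ± 0.06 and ICL1 at -1.81 ± 0.07. The glycerol kinase GUT1 changed by -1.90 ± 0.07 and the glycerol symporter STL1 by -1.89 ± 0.07, and 7 of 9 genes of glycerol uptake and breakdown were lower (camera adjusted p = 0.00238, or 0.513 with an estimated correlation). Counts adjusted over the list alone were the same except for mitochondrial ribosomal proteins (0 higher and 73 lower). Of 5155 called genes 3342 were higher and 1813 lower, or 2613 and 2497 with median centring, and the median gene changed by 0.23. Because glucose and glycerol libraries differ in run label, the medium and the run cannot be told apart in this contrast and in each other one against glucose within a strain.

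In YJM975, glycerol libraries held more mRNA for fermentation, sterol synthesis and ribosomes than the libraries labelled glucose. PDC6, a minor pyruvate decarboxylase, rose from 5.38 ± 0.562 to 1930.4 ± 112 TPM, PDC1 from 59.3 ± 4.67 to 7101 ± 455 TPM and FLO11 from 25.4 ± 2.49 to 2890.0 ± 109 TPM. IME1, the master regulator of meiosis, rose by 6.19 ± 0.07. Genes of glycolysis and fermentation rose for 18 of 21, at 2.93 relative to all genes (camera adjusted p = 6.75e-07, or 0.651 with an estimated correlation), with PGK1 at 4.24 ± 0.07. Sterol synthesis genes rose for 21 of 23 (camera adjusted p = 2.64e-06, or 0.651 with an estimated correlation), with ERG25 at 3.80 ± 0.06 and ERG3 at 3.66 ± 0.09. Cytosolic ribosomal protein genes rose for 126 of 139 (camera adjusted p = 9.61e-21, or 0.370 with an estimated correlation). CYC7 fell from 2822 ± 74.8 to 156 ± 5.21 TPM and HSP30 from 3840.2 ± 463 to 107 ± 14.9 TPM. Electron transport chain genes fell for 22 of 23 (camera adjusted p = 1.35e-06, or 0.157 with an estimated correlation), mitochondrial ribosomal protein genes for 60 of 73 (camera adjusted p = 5.12e-07, or 0.430 with an estimated correlation) and heat shock genes for 22 of 27 (camera adjusted p = 2.02e-05, or 0.688 with an estimated correlation). The stress gene BTN2 changed by -4.66 ± 0.08. STL1 rose by 2.60 ± 0.07, whereas GUT1 changed by -0.46 ± 0.07. For these lists, the counts adjusted over the list alone were the same except for mitochondrial ribosomal proteins (6 higher and 61 lower). limma called 5282 genes, 2597 higher and 2685 lower, and the median gene changed by -0.02.

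In RM11, ethanol libraries held more mRNA for amino acid synthesis than those labelled glucose and less for iron uptake. LYS9, the saccharopine dehydrogenase of lysine synthesis, rose from 15.2 ± 0.147 to 461 ± 4.59 TPM, and LYS12, LYS1 and LYS21, of the same pathway and chosen like LYS9 for their size of change, rose by 2.80 ± 0.05, 2.75 ± 0.08 and 2.17 ± 0.06 (LYS21 has a near-identical copy, LYS20). Amino acid synthesis genes rose for 51 of 61 (camera adjusted p = 1.51e-12, or 0.322 with an estimated correlation). Iron uptake genes fell for 25 of 28 (camera adjusted p = 1.07e-08, or 0.322 with an estimated correlation), with the cell wall siderophore-binding genes FIT2 at -2.83 ± 0.08 and FIT3 at -2.60 ± 0.08 and the siderophore transporter ARN1 at -2.81 ± 0.08. PDC1 rose by 4.22 ± 0.08, ENO2 by 4.15 ± 0.09, ADH2 by 1.49 ± 0.09 and the putative ammonium transporter ATO3 by 3.71 ± 0.07, with 11 of 14 genes of ethanol and acetate use (camera adjusted p = 5.28e-04, or 0.554 with an estimated correlation) and 15 of 21 of glycolysis and fermentation higher (camera adjusted p = 7.62e-08, or 0.322 with an estimated correlation). Cytosolic ribosomal protein genes rose for 125 of 139 (camera adjusted p = 5.14e-20, or 0.240 with an estimated correlation). Mitochondrial ribosomal protein genes fell for 70 of 73 (camera adjusted p = 3.01e-14, or 0.0987 with an estimated correlation), electron transport chain genes for 22 of 23 (camera adjusted p = 1.07e-08, or 0.0607 with an estimated correlation) and heat shock genes for 22 of 27 (camera adjusted p = 1.07e-08, or 0.322 with an estimated correlation). HAP4, the activator of respiratory genes, changed by -2.17 ± 0.06, and the zinc transporter ZRT1 by -3.25 ± 0.07. The counts of these lists adjusted over the list alone were the same except for amino acid synthesis (52 higher and 8 lower) and heat shock proteins and chaperones (1 higher and 23 lower). The contrast called 4379 genes, 2018 higher and 2361 lower, and the median gene changed by -0.03.

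In YJM975, ethanol libraries held more mRNA for amino acid synthesis, ribosomes, fermentation and sterol synthesis than those labelled glucose, and less for respiration and iron uptake. LYS9 rose from 1.79 ± 0.232 to 385 ± 20.2 TPM, LYS12 by 4.39 ± 0.05 and the aspartate kinase HOM3 by 3.77 ± 0.08, with 54 of 61 amino acid synthesis genes higher (camera adjusted p = 1.86e-06, or 0.589 with an estimated correlation). DPA10 rose from 40.7 ± 23.7 to 9367 ± 425 TPM, PDC6 by 7.93 ± 0.06, PDC1 by 6.27 ± 0.08 and the spore wall gene SPS100 by 5.73 ± 0.09. Genes of glycolysis and fermentation rose for 18 of 21 (camera adjusted p = 1.26e-04, or 0.589 with an estimated correlation). Of 139 cytosolic ribosomal protein genes 136 rose, at 2.30 relative to all genes (camera adjusted p = 1.68e-18, or 0.356 with an estimated correlation). Also, 35 of 39 ribosome biogenesis genes rose (camera adjusted p = 2.01e-05, or 0.447 with an estimated correlation). Sterol synthesis genes rose for 20 of 23 (camera adjusted p = 0.00472, or 0.610 with an estimated correlation), with ERG25 at 4.41 ± 0.06. CYC7 fell from 2822 ± 74.8 to 21.5 ± 1.12 TPM, CYC1 from 897 ± 30.3 to 154 ± 8.34 TPM and the alternative NADH dehydrogenase NDI1 changed by -2.74 ± 0.08. Genes of the electron transport chain fell for 22 of 23, at -2.17 relative to all genes (camera adjusted p = 2.14e-12, or 0.0121 with an estimated correlation), ATP synthase genes for 17 of 17 (camera adjusted p = 4.83e-09, or 0.0664 with an estimated correlation) and iron uptake genes for 19 of 28 (camera adjusted p = 1.35e-04, or 0.589 with an estimated correlation), with FIT2 at -3.50 ± 0.08 and the heme oxygenase HMX1 at -2.81 ± 0.09. ICL1 rose by 2.22 ± 0.07 and ADH2 by 3.19 ± 0.09. Counts adjusted over the list alone were the same. Of 5475 called genes 3564 were higher and 1911 lower, or 2736 and 2781 with median centring, and the median gene changed by 0.35.

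Ethanol and glycerol libraries carry the same run label, and RM11 had less mRNA for sporulation and ribosome biogenesis in ethanol than in glycerol. Of the 6 groups, RM11 in glycerol had the highest geometric means of HXK2, HXT1 and HXT3, 22.31 to 24.63 TPM. Doubt about the medium therefore covers these libraries too. SPS4 fell from 636 ± 48.8 to 2.80 ± 2.77 TPM. Also, 25 of 28 meiosis and sporulation genes fell, at -1.54 relative to all genes (camera adjusted p = 2.83e-06, or 0.224 with an estimated correlation), with SPS1 at -4.26 ± 0.13 and SSP2 at -3.61 ± 0.08. All 39 of 39 ribosome biogenesis genes fell (camera adjusted p = 2.74e-11, or 0.149 with an estimated correlation), with DBP2 at -3.42 ± 0.12. Also, 116 of 139 cytosolic ribosomal protein genes fell (camera adjusted p = 4.22e-04, or 0.706 with an estimated correlation), with RPL3 at -1.03 ± 0.07. HXK2 changed by -4.71 ± 0.12 and ADH2 by -2.05 ± 0.09. The formate dehydrogenase genes FDH1 and FDH2, near-identical copies whose reads can be split between them, changed by -7.04 ± 0.24 and -5.96 ± 0.14. LYS9 rose by 3.56 ± 0.05 and LYS1 by 2.88 ± 0.08, with 31 of 61 amino acid synthesis genes higher and 21 lower (camera adjusted p = 3.54e-05, or 0.642 with an estimated correlation). The peroxisomal citrate synthase CIT2 rose by 3.06 ± 0.08, MLS1 by 1.82 ± 0.08 and ICL1 by 1.67 ± 0.07, with 9 of 14 genes of the glyoxylate cycle and gluconeogenesis higher (camera adjusted p = 1.38e-04, or 0.532 with an estimated correlation). Mitochondrial ribosomal protein genes rose for 42 of 73 (camera adjusted p = 2.21e-10, or 0.177 with an estimated correlation) and electron transport chain genes for 18 of 23 (camera adjusted p = 3.39e-07, or 0.122 with an estimated correlation). HSP30 rose by 3.49 ± 0.10. For these lists, the counts adjusted over the list alone were the same. Of 4764 called genes 1348 were higher and 3416 lower, or 2475 and 2283 with median centring, and the median gene changed by -0.23.

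YJM975 showed the opposite direction for ribosome genes between these media. All 39 of 39 ribosome biogenesis genes were higher in ethanol than in glycerol (camera adjusted p = 2.17e-09, or 0.216 with an estimated correlation), with NSR1 at 2.65 ± 0.31. So were 139 of 139 cytosolic ribosomal protein genes (camera adjusted p = 1.32e-13, or 0.306 with an estimated correlation), with RPS22A at 1.93 ± 0.07. FLO11 fell from 2890.0 ± 109 to 63.4 ± 2.88 TPM. Electron transport chain genes fell for 20 of 23, at -0.88 relative to all genes (camera adjusted p = 7.58e-16, or 0.00377 with an estimated correlation), with CYC1 at -2.14 ± 0.05. Iron uptake genes fell for 18 of 28 (camera adjusted p = 3.16e-12, or 0.268 with an estimated correlation), with HMX1, FIT3 and FIT2 at -3.56 ± 0.09, -3.38 ± 0.08 and -2.98 ± 0.08. LYS9 rose by 4.58 ± 0.05, the homoaconitase LYS4 by 3.23 ± 0.07 and the glutamate dehydrogenase GDH1 by 3.15 ± 0.08, with 58 of 61 amino acid synthesis genes higher (camera adjusted p = 2.17e-09, or 0.379 with an estimated correlation). Purine and uracil synthesis genes rose for 19 of 22 (camera adjusted p = 0.00626, or 0.607 with an estimated correlation), with ADE4 at 2.27 ± 0.05. PCK1, the gluconeogenic carboxykinase, rose by 3.23 ± 0.08, ICL1 by 2.01 ± 0.07, the acetate transporter ADY2 by 3.93 ± 0.09 and the glycerophosphoinositol transporter GIT1 by 4.14 ± 0.06. FDH1 changed by -5.39 ± 0.24 and the weak-acid exporter PDR12 by -4.30 ± 0.09. The counts of these lists adjusted over the list alone were the same. limma called 4865 genes, 4039 higher and 826 lower, or 2215 and 2374 with median centring, and the median gene changed by 0.36.

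**Figure D3:**
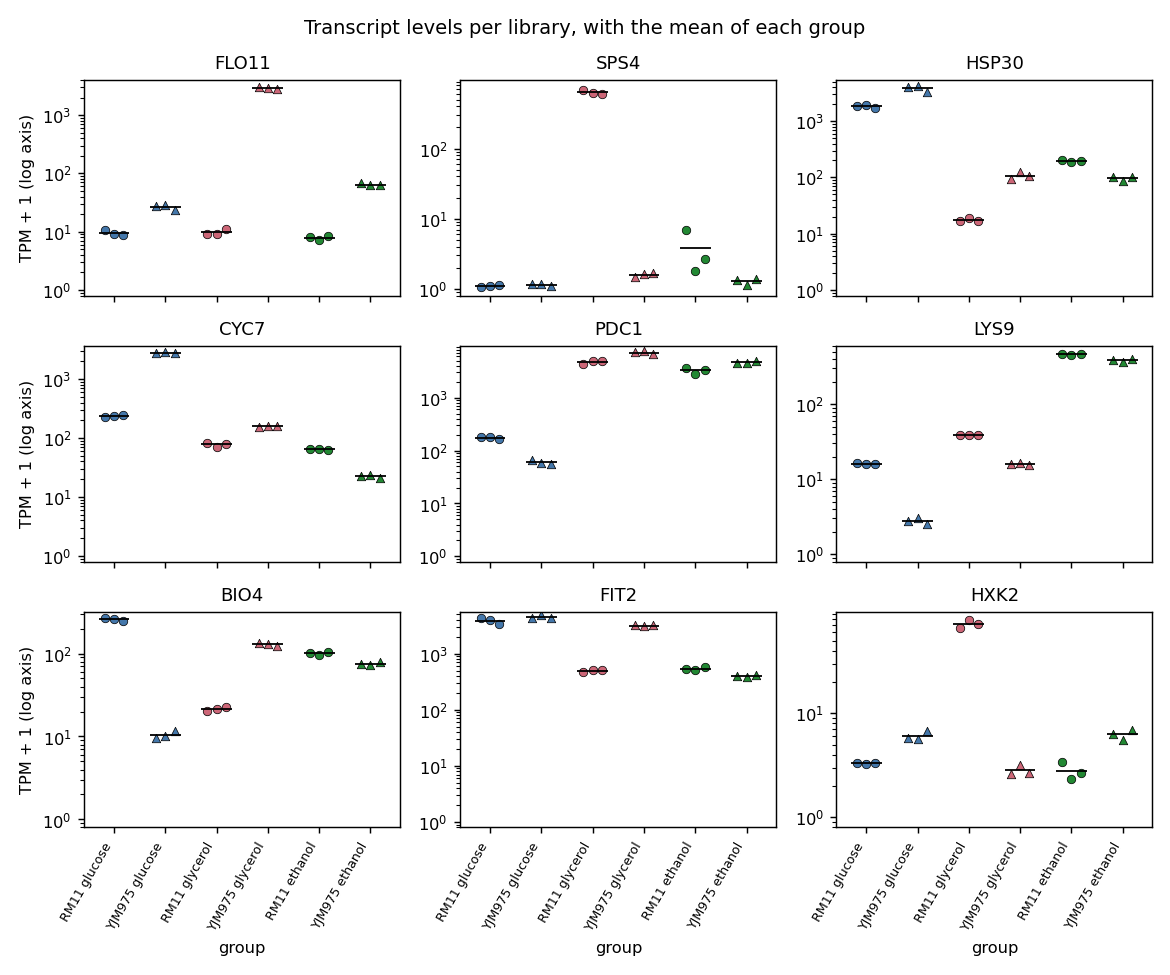
TPM + 1 (y axes, log scale) of 9 genes in the 6 groups (x axes), 1 point per library with the group mean as a line, colour for the medium and symbol for the strain. FLO11 averaged 2890.0 TPM in YJM975 in glycerol, SPS4 636 TPM in RM11 in glycerol, and LYS9 461 TPM in RM11 and 385 TPM in YJM975 in ethanol.

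The response to glycerol against glucose differed between the strains for 4938 genes in limma's test of the difference, YJM975 change minus RM11 change, 1990 higher and 2948 lower, or 2676 and 2411 with median centring. SPS4 differed by -8.70 ± 0.42 and SPR2 by -5.99 ± 0.26, with 23 of 28 meiosis and sporulation genes lower (camera adjusted p = 0.00139, or 0.701 with an estimated correlation), but IME1 was higher, at 4.33 ± 0.10. FLO11 differed by 6.75 ± 0.13, PDC6 by 7.34 ± 0.09 and STL1 by 4.49 ± 0.10. HXK2, which rose in RM11 and fell in YJM975, differed by -5.55 ± 0.17. Ribosome biogenesis genes were lower for 37 of 39, at -1.17 relative to all genes (camera adjusted p = 7.90e-08, or 0.596 with an estimated correlation), with DBP2 at -3.13 ± 0.17. Cytosolic ribosomal protein genes were higher for 103 of 139 (camera adjusted p = 4.30e-12, or 0.701 with an estimated correlation), with RPL3 at 2.17 ± 0.10. Glycolysis and fermentation genes were higher for 17 of 21 (camera adjusted p = 1.21e-05, or 0.701 with an estimated correlation), with PGK1 at 3.06 ± 0.10, and sterol synthesis genes for 17 of 23 (camera adjusted p = 2.83e-04, or 0.701 with an estimated correlation), with ERG3 at 4.20 ± 0.12. Histone genes were lower for 9 of 10 (camera adjusted p = 0.00139, or 0.596 with an estimated correlation), with HTB2 at -2.35 ± 0.08. Counts adjusted over the list alone were the same except for meiosis and sporulation genes (5 higher and 23 lower) and cytosolic ribosomal proteins (103 higher and 17 lower) and glycolysis and ethanol fermentation (18 higher and 3 lower) and sterol synthesis (17 higher and 4 lower). The median gene differed by -0.18, and a run effect equal in both strains leaves no trace in this test.

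For ethanol against glucose the difference between the strains' responses was called for 4843 genes, 3567 higher and 1276 lower, or 2416 and 2434 with median centring. Of 139 cytosolic ribosomal protein genes 136 were higher, at 1.69 relative to all genes (camera adjusted p = 9.50e-20, or 0.310 with an estimated correlation), with RPL3 at 3.83 ± 0.10. So were 37 of 39 ribosome biogenesis genes (camera adjusted p = 6.00e-07, or 0.325 with an estimated correlation), with NSR1 at 3.37 ± 0.43. Purine and uracil synthesis genes were higher for 20 of 22 (camera adjusted p = 0.00211, or 0.581 with an estimated correlation), with the CTP synthase URA7 at 3.15 ± 0.14. Electron transport chain genes were lower for 21 of 23 (camera adjusted p = 1.56e-13, or 0.00831 with an estimated correlation), with CYC7 at -5.08 ± 0.08 and COX5B at -2.40 ± 0.09. Heat shock genes were lower for 18 of 27 (camera adjusted p = 1.03e-05, or 0.581 with an estimated correlation), with the Hsp90 cochaperone CPR6 at -1.31 ± 0.08. DPA10 differed by 7.05 ± 0.31, and STL1, which fell in RM11 and rose in YJM975, by 2.91 ± 0.10. For these lists, the counts adjusted over the list alone were the same except for heat shock proteins and chaperones (7 higher and 18 lower). The median gene differed by 0.40.

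Between ethanol and glycerol, where all libraries share a run label, 5098 genes differed in response, 4129 higher and 969 lower, or 2381 and 2551 with median centring. All 39 of 39 ribosome biogenesis genes were higher, at 2.52 relative to all genes (camera adjusted p = 6.78e-11, or 0.146 with an estimated correlation), with DBP2 at 5.27 ± 0.17, NSR1 at 5.02 ± 0.43 and RPA49 at 4.69 ± 0.13, and 138 of 139 cytosolic ribosomal protein genes were higher (camera adjusted p = 6.44e-11, or 0.493 with an estimated correlation). Electron transport chain genes were lower for 21 of 23, at -1.51 (camera adjusted p = 1.93e-17, or 0.00244 with an estimated correlation), with COX7 at -1.76 ± 0.07, and ATP synthase genes for 17 of 17, at -1.16 (camera adjusted p = 1.36e-12, or 0.0176 with an estimated correlation), with ATP18 at -1.05 ± 0.10. Meiosis and sporulation genes were higher for 24 of 28 (camera adjusted p = 0.0117, or 0.495 with an estimated correlation), with SPS4 at 7.31 ± 0.42. FLO11 differed by -5.17 ± 0.13, HXK2 by 5.85 ± 0.17 and ADH2 by 3.48 ± 0.13. The counts of these lists adjusted over the list alone were the same. The median gene differed by 0.59. Across genes, which are not independent replicates, the responses of the strains, computed from separate libraries, correlated with r = 0.378 for glycerol against glucose, r = 0.693 for ethanol against glucose and r = -0.095 for ethanol against glycerol.

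**Figure D4:**
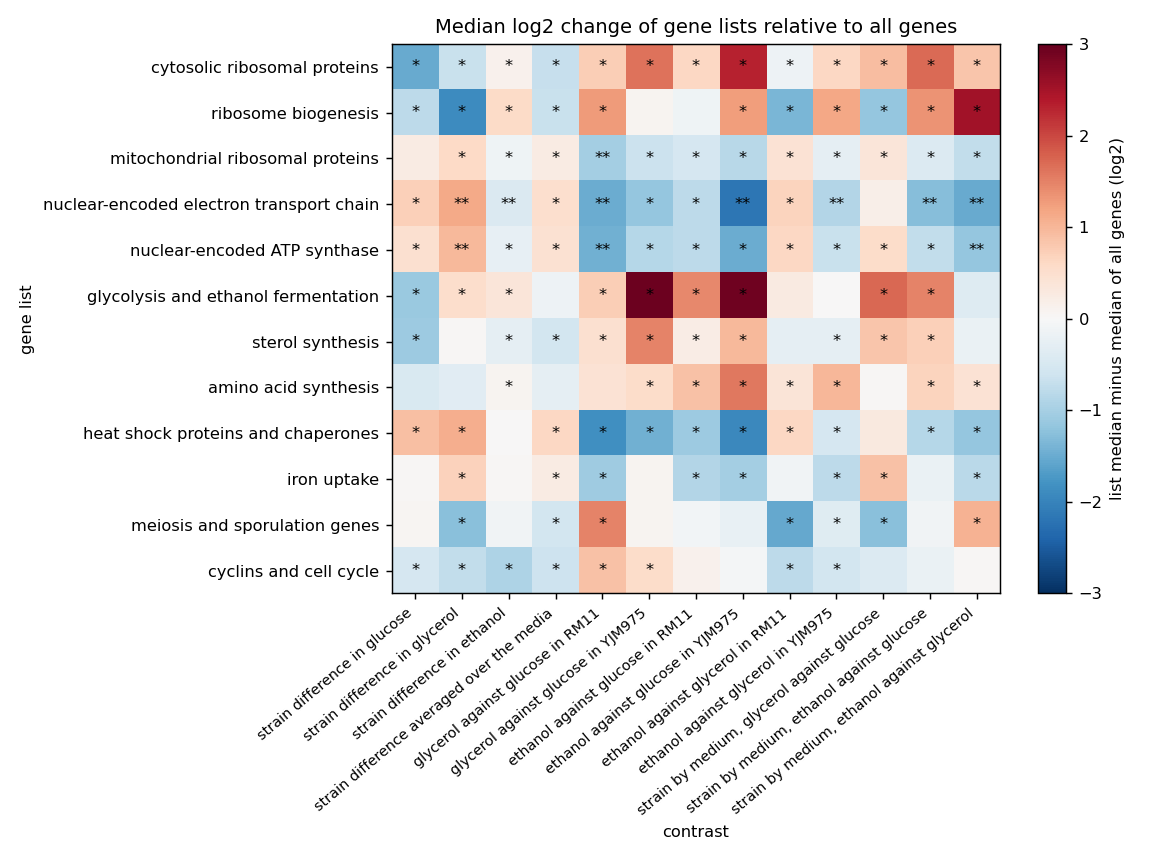
Median log2 change of 12 gene lists (y axis) in the 13 contrasts (x axis) minus the median of all genes, as colour from -3 (blue) to 3 (red). Stars mark lists called by camera with the preset correlation, and 2 stars those also called with an estimated correlation, such as the electron transport chain in ethanol against glycerol in YJM975 (-0.88).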

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

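The tests of the run, of gene length, of exchanged labels and of opposite directions under other scalings were chosen after the result was seen. Responses to a change of medium differed between the strains in limma's test of a difference of differences. For glycerol against glucose 4938 of 6309 genes differed in response, and 1398 of these were called in opposite directions in the 2 strains. Of the 1398, 391 were lower in RM11 and higher in YJM975, and 1007 the other way. Independent lists of the same sizes would share more, 746.3 and 1422.3. Chosen by the smaller of their 2 changes, BIO4, of biotin synthesis, changed by -3.60 on the log2 scale in RM11 and by 3.63 in YJM975, and the biotin transporter VHT1 by -3.71 and 3.22. For ethanol against glucose 4843 genes differed in response and 739 were called in opposite directions, among them STL1 at -1.55 and 1.36. Of the 739, 615 were lower in RM11 and higher in YJM975, and 124 the other way, again fewer than for independent lists (1333.7 and 611.3). For ethanol against glycerol 5098 differed and 2743 were called in opposite directions, among them NSR1 at -2.38 and 2.65. Of the 2743, 2475 were lower in RM11 and higher in YJM975, where independent lists of the same sizes would share 2186.9, and 268 the other way. Without the 50 top genes these were 1625 and 710, against 1304.1 and 479.4 for independent lists. Median centring, which balances higher and lower calls by construction, gave 1143 and 1277. Genes called in the same direction in both strains were 685 higher and 361 lower for ethanol against glycerol, fewer than independent lists would share (863.0 and 447.2). They were more than independent lists would share for glycerol against glucose, at 1822 and 1187 against 1375.7 and 771.6, and for ethanol against glucose, at 1757 and 1399 against 1140.0 and 715.1.

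Ribosomal protein and glycolytic transcripts were lower, and respiratory chain transcripts higher, in the libraries labelled glucose than in those labelled ethanol, in both strains, but with an estimated correlation camera called only the respiratory chain in YJM975 (adjusted p = 0.0121) of these 3 lists. A run effect equal in both strains cancels in the difference of responses, where 136 of 139 ribosomal protein genes were called higher. The part that differs therefore cannot come from an equal run effect. A run effect of unequal size in the 2 strains stays open, since run and medium are confounded there too. The shared part, a relative median of 0.624 in RM11, cannot be told apart from the run, since all glucose libraries carry 1 run label and all others another. Gene length is argued against by the 87.9% or more of each relative list median kept with the length trend removed. The ratio of ICL1, FBP1 and PCK1 to HXK2, HXT1 and HXT3 (geometric means) was above 1 in every library. Exchange of labels alone predicts a ratio below 1 in some group labelled glycerol or ethanol. The lowest there was 11.16, which argues against exchange as the only cause. Exchange combined with glucose cultures with little glucose left, such cultures alone and cultures from elsewhere stay open as candidate explanations. In RM11 the ratio was 250.8 to 271.41 in glucose, 93.93 to 103.64 in ethanol and 11.16 to 12.53 in glycerol, the lowest of all groups. In YJM975 glucose (55.4 to 65.6) and ethanol (56.22 to 58.87) overlapped, and glycerol lay at 21.42 to 24.92.

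The strains differed by 2-fold or more at 298 genes in ethanol, against 1724 in glucose and 2179 in glycerol, or 158, 1060 and 1516 with a pseudocount of 5. A larger spread between replicates in ethanol is argued against by the ratio of its median SD to that of the other groups, 1.045. Scaling is argued against by the 3 other scalings tried, under which the ethanol count was at most 22.9% of the smaller of the other counts. Growth of the strains may be more alike in ethanol, as a hypothesis, and growth rates were not analysed here.

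In 1 strain, 10 transcripts stayed below 0.5 TPM in every library while each group mean of the other strain was 5 TPM or more, PHO11, YEL077W-A, YER188W, YIL177W-A, YJL225W-A and FLO10 in RM11 and MAL13, MAL11, YIR042C and YPL257W in YJM975, chosen by these limits. Of the 7 placed on the S288C assembly, 6 (85.7%) lay within 10 genes of a chromosome end, against 240 of 5760 other tested genes (4.2%, odds ratio 138.0, two-sided Fisher's exact p = 3.83e-08). MAL11 and MAL13 are neighbours, 5 and 6 genes from an end, and Fisher's test counts them as independent genes. The genes near 0 in 1 strain may be absent from, or diverged in, that strain. Reads shared with a near-identical copy stay open, since 1 of 7 (14.3%, exact 95% interval 0.4 to 57.9%) has one, PHO11 with PHO12. YIL177W-A and YJL225W-A held identical values in every library.

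Other splits of the libraries were tried for each count of called genes, in limma fits on the libraries of the contrast. Comparisons of 3 with 3 libraries allow 10 splits, so the share of splits as large is never below 0.1. The strain difference called 5249 genes in glucose, 5421 in glycerol and 2778 in ethanol, with 0 as the highest of the other splits. In RM11 and YJM975, glycerol against glucose called 5198 and 5183, ethanol against glucose 4283 and 5433, and ethanol against glycerol 4658 and 4794, again with 0 as the highest other. For the strain difference averaged over the media and the 3 differences of responses, only the real split among 100 drawn called as many. With 100 draws, chance is unlikely for the count of the average but is not excluded. Strain labels were shuffled within each medium, so a draw can exchange the strains in 1 medium alone and still hold a real difference. The shuffle removes strain differences as a whole and does not make the strains' responses equal. It therefore cannot test the 3 differences of responses, and no conclusion on them is drawn from it. The real and highest other counts were 5344 and 2685 for the average. They were 4922 and 3088 for glycerol against glucose, 4814 and 4152 for ethanol against glucose, and 5081 and 4647 for ethanol against glycerol.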

How the results depend on the processing

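Removal of a length trend, fits without the glucose libraries and camera with a variance trend are tests chosen after the result was seen. Totals of called genes stayed within 1.5 times in each contrast under each alternative run. Each gene with a named change kept its direction and call in each setting that tested it. The split into higher and lower genes moved with scaling, and the cause was not tested. Median centring and quantile normalization bring that split near balance by construction, and so say little on its direction. Without the 50 top genes the larger side stayed in 10 of 13 contrasts, with 1637 higher and 3535 lower in glucose, 1774 and 3471 in glycerol and 1535 and 3749 averaged. It turned for the strain difference in ethanol (1487 and 1649), glycerol against glucose in YJM975 (3023 and 2294) and the difference of responses to glycerol against glucose (2646 and 2335). The next paragraph gives the counts of called genes that moved by over 1.5 times, with pairs as higher and lower genes. With smaller moves, the larger side also turned in other contrasts, among them glycerol against glucose in RM11 (3342 and 1813, or 2513 and 2704 with quantile normalization), the difference of that response (1990 and 2948, or 2676 and 2411 with median centring) and the strain difference in ethanol (1692 and 1335, or 1576 and 1700). Counts at 2-fold or more fell with a pseudocount of 5, from 298 to 158 for the strain difference in ethanol and from 1724 to 1060 in glucose. Their split moved as well, with 576 and 667 in glucose and 650 and 816 in glycerol under quantile normalization.

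Median centring gave 2607 genes higher for the strain difference in glucose, 2643 and 2607 in glycerol and 2535 and 2745 averaged. It gave 2475 higher for ethanol against glycerol in RM11 and 2215 and 2374 in YJM975. Differences of responses then gave 2434 lower for ethanol against glucose, and 2381 and 2551 for ethanol against glycerol. Quantile normalization gave 2724 and 2380 in glucose, 2915 and 2366 in glycerol and 2831 and 2346 averaged. It gave 2915 lower for ethanol against glucose in YJM975, and for ethanol against glycerol 2715 and 2183 in RM11 and 2100 and 2442 in YJM975. Its differences of responses were 2207 and 2539 for ethanol against glucose and 2145 and 2804 for ethanol against glycerol. Rescaling without the 50 top genes gave 1774 higher in glycerol and 1535 averaged. It gave 1681 lower for ethanol against glycerol in YJM975 and 1748 for the difference of that response. With the length trend removed the strain counts were 2518 and 2417 in glucose, 2537 and 2395 in glycerol and 2445 and 2501 averaged. Ethanol against glycerol then gave 2366 and 2151 in RM11 and 2107 and 2376 in YJM975. The differences of responses were 2262 and 2417 for ethanol against glucose and 2194 and 2504 for ethanol against glycerol.

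Camera called 205 list tests at the preset correlation and 11 with an estimated one, of 455 tests. Other settings with all these tests called 199 to 205, the filter at 10 TPM 189 of 442, and fits on the groups compared only 178 of 420. Under quantile normalization the relative median reversed for ATP synthase in the strain difference in glucose (-0.143) and for glycolysis and ethanol fermentation in the strain difference in glycerol (-0.047), and the cause was not tested. Same-numbered libraries of different groups had deviations correlated between -0.217 and 0.159, and a library correlated best with its own number in 19 of 90 cases. No sign of pairing by number was seen, which does not show that the cultures were handled apart. With the number as a block, 5249 genes were called for the strain difference in glucose. Leaving out 1 library at a time gave 2642 to 3128 for the strain difference in ethanol, the widest relative range of the 13 totals. With depth unknown, no bound can be given for genes near 0.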

Other observations

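Picked for their opposite changes, the biotin transporter gene VHT1 and the biotin synthesis gene BIO4 fell in RM11 from glucose to glycerol, VHT1 from 375 ± 31.5 to 27.8 ± 2.38 TPM and BIO4 from 258 ± 13.2 to 20.4 ± 1.23 TPM (SD, n = 3). In YJM975 VHT1 rose from 34.2 ± 0.0973 to 329 ± 42.6 TPM and BIO4 from 9.51 ± 1.01 to 129 ± 5.48 TPM. In limma's test of the difference, BIO4 stood at 7.23 ± 0.10 and VHT1 at 6.93 ± 0.13. In ethanol, 13 of 19 thiamine synthesis genes were higher in YJM975 than in RM11 (camera adjusted p = 0.00819, or 0.462 with an estimated correlation). Counts adjusted over the list alone were the same except for thiamine synthesis (14 higher and 4 lower).

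LEU2, of leucine synthesis, was higher in YJM975 by 1.11 ± 0.07 in glucose, 1.09 ± 0.07 in glycerol and 1.08 ± 0.07 in ethanol (limma adjusted p = 3.83e-11, 3.96e-11 and 6.18e-10). HO, the mating-type switching endonuclease, was listed at 0 in each RM11 library and reached 0.437 TPM at most in YJM975. URA3, of uracil synthesis, was listed at 0 in each YJM975 library and reached 0.189 TPM at most in RM11.

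Of the 35 lists tested, 5 were called by camera in none of the 13 contrasts. Their lowest adjusted p was 0.0660 for peroxisome and fatty acid oxidation, 0.0667 for haploid-specific and mating genes, 0.0717 for hexose transporters, 0.190 for phosphate response and 0.431 for galactose use.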
